A study of Arabidopsis thaliana with 24 samples.

How the data were processed

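Leaf RNA from 24 samples of 4-week-old Arabidopsis thaliana was hybridised to Affymetrix ATH1 arrays, 1 array per sample. The samples fall into 8 groups of 3 arrays: mock-treated Col-0, and Col-0 and 6 mutants (coi1, ein2, npr1, pad2, pad4 and sid2) collected 24 h after inoculation with Pseudomonas syringae ES4326. The labels number the arrays of a group from 1 to 3 but do not state that these are separate plants or separate experiments, so p values measure only the spread between these samples. For sid2 the labels give seed stratification as 2 to 3 days and for the other genotypes as 3 days, with growth described in other words. Any batch behind that difference cannot be told apart from the sid2 group.

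The authors' values are signal intensity per probe set on a linear scale, made with MAS5 and GCOS per the submitters' processing notes; the versions are not given in the sources used here. Every array had been scaled by the authors to one mean: after trimming 2% of probe sets at each end, the array means lay between 100.009 and 100.012. No detection calls were used. Of 22810 probe sets, 64 controls were left out of the tests, and 22746 were analysed. A probe set was kept if its signal exceeded the 40th percentile of its own array on at least 3 of the 24 arrays, which left 15961. Signals under 1 were set to 1 and log2 transformed, and stayed on the authors' scale. The 40th percentile of an array, between 9.22 and 19.5, served as its floor. Where all 3 arrays of a group lay at or under the floor, a fold is given only as a bound against the floor. Where some did, the fold is given after raising values to the floor.

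Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit, eBayes with a trend) in 1 fit of the 8 groups to all 24 arrays, with 16 residual degrees of freedom and a prior of 4.97. Benjamini-Hochberg adjustment ran over all probe sets kept, per comparison, and a probe set was called at an adjusted p under 0.05. There were 10 comparisons: infected against mock-treated Col-0, each mutant against infected Col-0, and pad4, npr1 and coi1 against sid2. An F test asked for any difference among the 7 infected genotypes. All p values are two-sided. On simulated data with 3 against 3 arrays in the same fit, 5.67% of probe sets changed by 0.5 (log2) were recovered, 36.4% of those changed by 1 and 72.4% of those changed by 2, and 5.86% of calls were false.

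Groups, comparisons, gene lists, the rule for named genes and the alternatives to be tried were fixed before the data were examined. Named genes are the 5 largest rises and 5 largest falls among called probe sets matched to 1 gene with a symbol and with arrays that do not overlap between the groups, and up to 4 called members of each list; not every list member taken by this rule is printed in the report. Genes with a group wholly at the floor were left out of the first part, which the rule as first written did not ask; they appear through the lists. A gene with several probe sets was read from the probe set with the highest mean over all arrays. Of the probe sets kept, 8738 were listed with 1 gene, 333 with several and 6890 with none. Of those with 1 gene 1217 had a symbol, so most changes are not named here. Of 366 list genes 54 had a named probe set. None of the 6 genes that the mutants are named for did.

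The 8 lists with at least 3 measured genes (SA regulation and synthesis, SA response, pattern-triggered immunity, photosynthesis, auxin, glutathione and sulfate assimilation, phenylpropanoid and anthocyanin, and reference genes) were tested with camera at a preset correlation of 0.01, adjusted over the 8 lists of a comparison. Camera with an estimated correlation and fry were run beside it. Of all list calls, 2 held with an estimated correlation: SA response in sid2 against Col-0 and in npr1 against sid2. Smaller lists were described gene by gene. For each mutant, infection-responsive sets were chosen from mock-treated Col-0 and the other 5 mutants, at an adjusted p under 0.05 and at least 2-fold, so that neither infected Col-0 nor that mutant chose them. Correlations between mutants' differences from Col-0 are across probe sets, which are not independent replicates, and have no test. They were set beside groups simulated with no change that share the 3 Col-0 arrays. A further 18 families of genes with like symbols were chosen after the annotation had been seen and before their values were tested.

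Array numbers were checked for pairing by correlating residuals of same-numbered arrays. In pad4 against sid2 (r = 0.17, 0.12 and 0.21) and npr1 against sid2 (0.16, 0.22 and 0.15) every pair exceeded 0.1; each of the other 8 comparisons had a pair under 0.1. The array number was also fitted as a block in every comparison. For these 2, values with it are given where they change a call or move a count by over 1.5 times. For the other 8, counts that it moved are given beside the other alternatives. Residuals of 22 of 24 arrays correlated best with their own number in other groups, so pairing may reach beyond these 2 comparisons. Alternatives were quantile normalization, centring each array on its median, no filter, a 60th percentile filter, log2 of the value plus 32, no trend, array weights, fits of the groups compared alone, the block, a 2-fold threshold, probe sets listed with 1 gene only, and each array left out in turn. Leaving out ein2 array 3 and pad4 array 3 together was added after the data had been seen. RNA quality was compared through the 3' to 5' signal ratios of control genes with exact permutation tests. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.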

Results

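Transcript levels were measured in leaves of 4-week-old Arabidopsis thaliana plants on 24 ATH1 arrays, 3 for each of 8 groups. One group was mock-treated wild type (Col-0). The other 7 groups were sampled 24 h after inoculation with the leaf pathogen Pseudomonas syringae ES4326: Col-0 and 6 mutants in the same background. The coi1 mutant lacks the receptor for jasmonate and for the bacterial toxin coronatine, and ein2 does not respond to ethylene. The npr1 mutant lacks a receptor that carries salicylate signals, pad4 lacks a lipase-like protein that promotes salicylate accumulation, and sid2 lacks the isochorismate synthase that makes most pathogen-induced salicylate. The pad2 mutant is deficient in glutathione. No mutant was mock-treated, so a difference between genotypes that exists without infection cannot be separated from a difference in the response. Array medians ran from 18.6 to 34.3 signal units, and arrays of a group correlated with r between 0.910 and 0.960 across probe sets, which are not independent replicates. The number of arrays limits the precision. Below, values are mean signals ± SD with n = 3 arrays per group, and the floor is the 40th percentile of an array's own signals. A gene named for its size of change had no overlap between the arrays of the 2 groups compared.

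**Figure D1:**
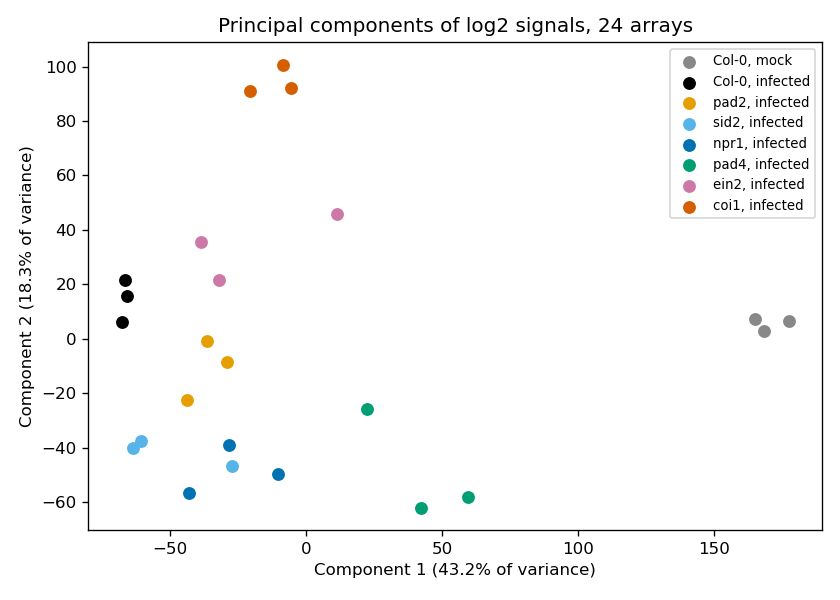
Principal components of log2 signals; each point is 1 of 24 arrays, coloured by group, with component 1 (43.2% of variance) on the x axis and component 2 (18.3%) on the y axis. The 3 mock arrays lie at the right, between 165 and 177 on component 1, and the 3 pad4 arrays are the infected arrays nearest to them, between 22.3 and 59.4.

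The first comparison, infected against mock-treated Col-0, asks how infection alters wild-type leaves. BSMT1 (AT3G11480), which makes methyl salicylate, rose from 12.7 ± 20.4 to 3720.3 ± 432 (adjusted p = 1.9e-09). It exceeded the floor on 1 of the 3 mock arrays, and with values raised to the floor the rise was 167-fold. JRG21, a jasmonate-regulated oxygenase, rose 62.1-fold from 82.6 ± 47.9 to 4626 ± 500.35, and the subtilisin-like protease gene SBT3.3 rose 56.9-fold from 28.5 ± 2.88 to 1619 ± 134. GH3.3, which conjugates auxin to amino acids, rose 29.1-fold from 23.5 ± 6.04 to 684 ± 171. The calmodulin-like CML38 rose from 9.32 ± 8.21, above the floor on 1 of 3 arrays, to 236 ± 122 (11.9-fold with values raised to the floor). The largest falls included 3 enzymes of chlorophyll synthesis. PORB fell from 691 ± 295 to 11.9 ± 9.91 and CHLI2 from 192 ± 19.7 to 7.51 ± 5.63, each above the floor on 2 infected arrays and 44.5-fold and 17.9-fold lower with values raised to it. CHLM fell 32.9-fold from 1654 ± 358 to 49.8 ± 6.40. XTH32, which remodels cell wall xyloglucan, fell 77.3-fold from 852 ± 52.7 to 11.1 ± 1.38, and the glutathione transferase gene GSTU20 fell 48.1-fold from 1957 ± 379 to 44.9 ± 24.98.

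All 9 measured photosynthesis genes fell in infected Col-0, and 9 passed when adjusted over the list alone. SBPASE and PRK, enzymes of the Calvin cycle, fell from 4147 ± 617 to 184 ± 24.6 and from 5845 ± 156 to 368 ± 79.2. The light-harvesting gene LHCB4.2 fell from 6787 ± 775 to 858 ± 222 and PSAN of photosystem I from 5438 ± 375 to 557 ± 114. The list fell as a set (median log2 -2.30, or -2.06 relative to all probe sets; camera adjusted p = 3.4e-05; adjusted p = 0.18 with an estimated correlation). Of 21 listed SA response genes 3 had a named probe set. All 3 rose, and 3 passed when adjusted over the list alone. The glutaredoxin gene GRX480 rose from 50.1 ± 3.27 to 976 ± 65.2, the glycosyltransferase gene UGT76B1 from 81.9 ± 107 to 1232 ± 260, and the transcription factor gene WRKY53 from 79.7 ± 15.3 to 262 ± 26.7. Of 21 listed SA regulation and synthesis genes 4 had a named probe set. Of these 3 rose, and 3 passed when adjusted over the list alone: BSMT1, SARD4 of pipecolate synthesis (284 ± 56.8 to 1722 ± 166) and SAG101, a partner of EDS1 (40.7 ± 6.20 to 202 ± 46.1). Both sets rose (adjusted p = 0.0099 and 0.014; adjusted p = 0.060 and 0.062 with an estimated correlation). Of 5 genes of pattern-triggered immunity 3 rose, 3 when adjusted over the list alone, and the set rose (adjusted p = 0.023; adjusted p = 0.31 with an estimated correlation). PUB23 rose from 20.7 ± 4.36 to 232 ± 71.8 and the kinase gene BIK1 from 108 ± 22.8 to 325 ± 118. These 3 set calls ended when each array was centred on its median (adjusted p = 0.05003, 0.0598 and 0.0598), and that of pattern-triggered immunity also with a 60th percentile filter (0.054).

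Single genes of other pathways also changed with infection. OPCL1 of jasmonate synthesis rose from 202 ± 11.2 to 815 ± 39.9, and JMT, which methylates jasmonate, from 62.8 ± 20.3 to 568 ± 119.6. IGPS of tryptophan synthesis rose from 383 ± 59.97 to 1662 ± 210.4. The senescence regulator gene WRKY6 rose from 27.9 ± 5.23 to 338 ± 75.4, and the dehydrin gene COR47 from 306 ± 31.4 to 1346 ± 544. BCAT4 of aliphatic glucosinolate synthesis fell from 1522 ± 366 to 71.3 ± 35.5, and PDF1.2B, a plant defensin gene, fell from 123 ± 121 to the floor on all 3 infected arrays, at least 7.59-fold lower. Among 3 auxin genes GH3.3 and GH3.5 rose and IAA29 fell, 3 when adjusted over the list alone (set adjusted p = 0.30). Among 3 genes of glutathione and sulfate assimilation ATPS4 and GR1 rose while SIR, sulfite reductase, fell from 1011 ± 123 to 399 ± 23.2, 3 when adjusted over the list alone (set adjusted p = 0.44). None of the 3 phenylpropanoid and anthocyanin genes passed, 0 when adjusted over the list alone (set adjusted p = 0.93). None of the 3 reference genes passed, 0 when adjusted over the list alone (set adjusted p = 0.75). UBC21 stood at 154 ± 17.58 infected and 140 ± 5.93 mock, and passed as a rise when arrays were centred.

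In this comparison 10106 of 15961 probe sets were called, 4227 higher and 5879 lower, 7375 of them by at least 2-fold. The arrays did not overlap for 70.5% of all probe sets, against 10% by chance. The median of all probe sets moved by -0.25 (log2) on the authors' scale, 0.12 after quantile normalization and 0.50 after centring. The split turned to 5289 higher and 4542 lower and to 7147 higher and 3352 lower, so the balance of rises and falls depends on the scale. The ratio of 3' to 5' GAPDH signal was 0.965 in infected and 0.837 in mock-treated Col-0 (exact permutation p = 0.1, the smallest that 3 against 3 arrays allow).

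**Figure D2:**
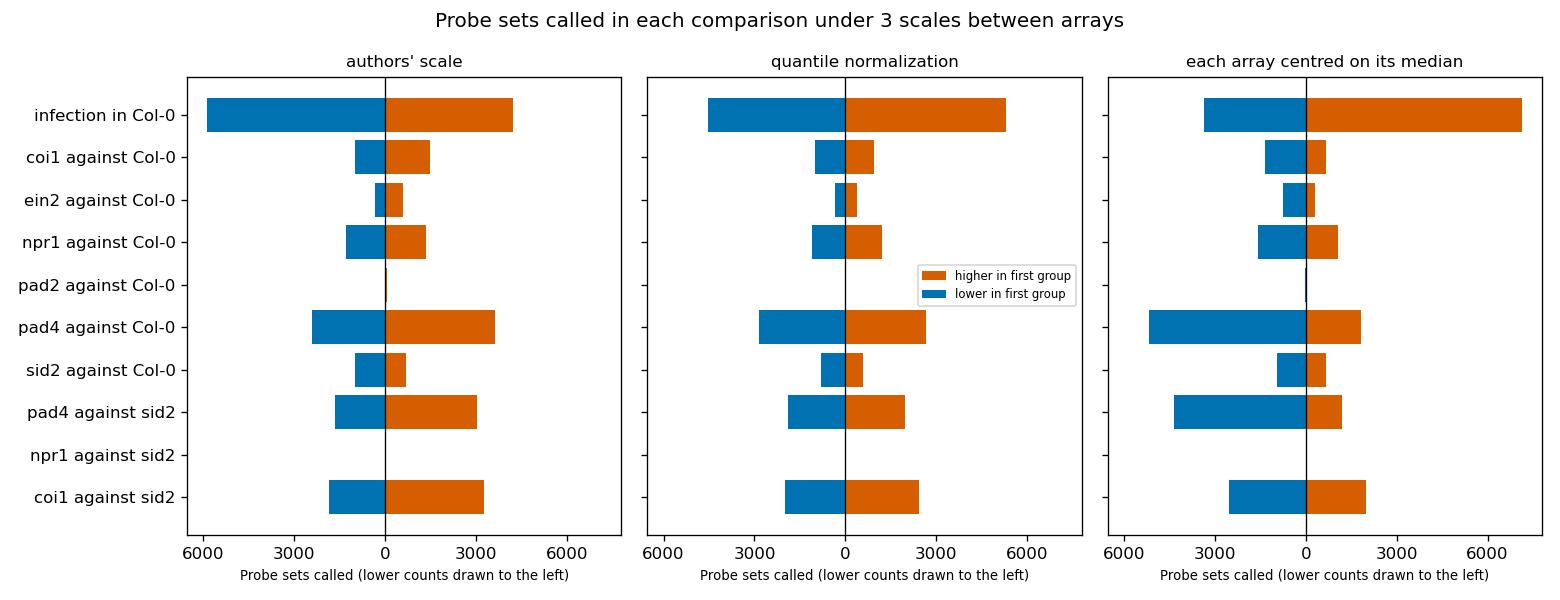
Number of probe sets called in each of the 10 comparisons (x axis; bars to the right, higher in the first group; bars to the left, lower) on 3 scales between arrays, 1 per panel. In infected against mock-treated Col-0 the authors' scale gave 4227 higher and 5879 lower, and centring gave 7147 and 3352; npr1 against sid2 gave 21 calls on the authors' scale.

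The comparison of coi1 with Col-0, both infected, addresses what the jasmonate receptor contributes during infection. BSMT1 stood at 8.30 ± 4.13 in coi1 and 3720.3 ± 432 in Col-0 (adjusted p = 7.9e-08; above the floor on 1 coi1 array, 330-fold lower with values raised to the floor). JMT lay at the floor on all 3 coi1 arrays, at least 51.8-fold lower than the 568 ± 119.6 of Col-0 (adjusted p = 5.3e-11). UGT76E12, a glycosyltransferase gene, stood at 10.1 ± 7.92 against 1200.5 ± 240.2 (above the floor on 2 coi1 arrays, 89.4-fold lower with values raised to it). GRX480 stood at 69.6 ± 10.1 against 976 ± 65.2 (14.1-fold lower, adjusted p = 1.7e-11) and the peroxidase gene Prx37 at 17.3 ± 4.17 against 264 ± 181. BGLU31 (10.3 ± 4.43 against 229 ± 139; above the floor on 1 coi1 array, 16.3-fold) and OPCL1 (186 ± 19.6 against 815 ± 39.9) were also lower. In mock-treated Col-0, GRX480 stood at 50.1 ± 3.27 and OPCL1 at 202 ± 11.2. Higher in coi1 were the protease gene NANA (118 ± 54.7 against 8.77 ± 2.21; above the floor on 1 Col-0 array, 10.4-fold), SKU5 (102 ± 40.4 against 22.8 ± 15.7), and GSTU27 (403 ± 58.3 against 88.4 ± 10.4). So were CYP71B29 (84.5 ± 17.7 against 18.24 ± 13.6; above the floor on 2 Col-0 arrays, 4.34-fold) and SAL2 (204 ± 52.0 against 48.9 ± 13.2). The call of CYP71B29 ended without Col-0 array 2 (adjusted p = 0.084), and that of SAL2 without Col-0 array 2 (0.071) or coi1 array 3 (0.065).

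List members moved in both directions in coi1. In the SA response list GRX480 was lower, WRKY53 was higher (601 ± 119.98 against 262 ± 26.7; adjusted p = 0.058 without coi1 array 1) and UGT76B1 did not pass (631 ± 185 against 1232 ± 260). Of the 3 genes 2 passed when adjusted over the list alone. The set had a median log2 of -0.99 and was not called (camera adjusted p = 0.091; fry adjusted p = 2.8e-06). Of the SA regulation and synthesis genes 1 of 4, BSMT1, was lower, 1 when adjusted over the list alone (set adjusted p = 0.14). PRK (1439 ± 161 against 368 ± 79.2), SBPASE (488 ± 66.1 against 184 ± 24.6) and RCA were the 3 of 9 photosynthesis genes that were higher, 3 when adjusted over the list alone (set adjusted p = 0.091, 0.0013 after quantile normalization and 0.040 without a filter). RCA did not pass with centred arrays (adjusted p = 0.17) or without a filter (0.070), nor without coi1 array 2 (0.061), Col-0 array 2 (0.052) or Col-0 array 3 (0.065). Without Col-0 array 3 the photosynthesis set was called higher and the auxin set lower (both adjusted p = 0.043). Of the 3 auxin genes 1, GH3.3, was lower, 2 when adjusted over the list alone (set adjusted p = 0.091). GH3.3 did not pass without coi1 array 1 (adjusted p = 0.052), coi1 array 3 (0.10) or Col-0 array 2 (0.073). PUB23 was the 1 of 5 genes of pattern-triggered immunity that differed (73.6 ± 44.2 against 232 ± 71.8), 1 when adjusted over the list alone (set adjusted p = 0.67). IGPS was lower (804 ± 101 against 1662 ± 210.4). Of the 15961 probe sets 2470 were called, 1493 higher and 977 lower, and 1594 without coi1 array 1. With a median of all probe sets of 0.16, the split was 956 higher and 1010 lower after quantile normalization and 671 and 1343 after centring. The arrays of 38.7% of probe sets did not overlap, against 10% by chance.

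In ein2 against Col-0, which concerns the ethylene response, the cytokinin response regulator gene RR16 was lower (15.3 ± 8.88 against 95.7 ± 6.78; above the floor on 2 ein2 arrays, 5.91-fold). Also lower were UGT71B5 (23.7 ± 11.2 against 118 ± 12.2; above the floor on 2 ein2 arrays, 5.34-fold), TBL45 (65.4 ± 18.7 against 285 ± 69.1, 4.39-fold), UGT76E12 (273 ± 139 against 1200.5 ± 240.2, 4.80-fold) and OCT1 (4.55 ± 6.22 against 21.8 ± 6.24; above the floor on 1 ein2 array, 1.70-fold). Higher were the defensin-like gene PDF1.4 (276 ± 95.7 against 47.1 ± 10.4, 5.72-fold), ARPN (37.9 ± 18.16 against 7.50 ± 5.15, 3.24-fold), NANA (58.2 ± 49.8 against 8.77 ± 2.21, 4.28-fold) and PPR596 (18.5 ± 7.50 against 5.77 ± 5.11, 1.61-fold). The last 3 were above the floor on 1 Col-0 array. The calls of these 4 genes, UGT76E12 and OCT1 ended without ein2 array 3 (adjusted p from 0.080 to 0.20) and those other than NANA without Col-0 array 1 (0.058 to 0.17). Those of UGT76E12, OCT1, PDF1.4 and PPR596 also ended without Col-0 array 2 (0.067 to 0.12). The first 3 of these ended without Col-0 array 3 too (0.078 to 0.10). Without ein2 array 1 OCT1 (0.092) and PPR596 (0.0996) did not pass, nor without ein2 array 2 UGT76E12 (0.061) and PDF1.4 (0.062). In the fit of the groups compared ARPN (0.11), NANA (0.072), OCT1 (0.12) and PPR596 (0.21) did not pass. UGT76E12 (0.062) and OCT1 (0.067) did not pass with array weights, UGT76E12 (0.061) and PDF1.4 (0.052) without a trend, or UGT76E12 (0.053) and PPR596 (0.051) without a filter. PPR596 was not called after quantile normalization (0.058) or with log2 of the value plus 32 (0.11) either. Photosynthesis genes were higher in ein2: 7 of 9 passed, and 9 when adjusted over the list alone. SBPASE stood at 531 ± 205 against 184 ± 24.6, PSBY at 2108 ± 238 against 1124 ± 49.6 and PRK at 1134 ± 496 against 368 ± 79.2. The list was higher as a set (median log2 0.90, or 0.81 relative to all probe sets; camera adjusted p = 1.8e-08; adjusted p = 0.17 with an estimated correlation). The mock values of these 3 genes were 4147 ± 617, 5594 ± 934 and 5845 ± 156. BCAT4 (432 ± 175 against 71.3 ± 35.5, adjusted p = 0.028) was higher, and did not pass without ein2 array 2 (0.069), ein2 array 3 (0.13), Col-0 array 1 (0.051) or Col-0 array 2 (0.14). The call of PRK also ended without ein2 array 3 (adjusted p = 0.063). Array 3 of ein2 correlated with the mean of the mock arrays at r = 0.769, the other ein2 arrays both at 0.692. The GAPDH 3' to 5' ratio was 0.839 in ein2 and 0.965 in Col-0 (exact permutation p = 0.1). Among other lists, 1 of 3 SA response genes passed only when adjusted over the list alone (set adjusted p = 0.78), and no auxin gene passed (set adjusted p = 0.78).

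The fit called 921 probe sets in ein2, 583 higher and 338 lower, with a median of all of 0.089 and 25.1% without overlap, against 10% by chance. The count fell to 261 without ein2 array 3, with 120 higher and 141 lower, and stood at 518, 417 and 509 without Col-0 array 1, 2 or 3. Centring turned the split to 299 higher and 754 lower.

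The npr1 mutant was compared with Col-0 to ask which infected-leaf transcripts depend on this salicylate receptor. UGT73D1 (23.4 ± 7.53 against 266 ± 118, 11.0-fold lower), the invertase-family gene cwINV6 (23.8 ± 10.2 against 208 ± 59.4, 9.14-fold) and UGT76B1 (187 ± 63.9 against 1232 ± 260, 6.75-fold) were lower in npr1. CML43 stood at 5.70 ± 5.27 against 39.6 ± 1.55, above the floor on 1 npr1 array and 3.51-fold lower with values raised to the floor. GLR2.8 was lower as well (10.3 ± 6.04 against 37.5 ± 5.86; above the floor on 1 npr1 array, 3.03-fold; adjusted p = 0.066 without npr1 array 2). Higher were CSLA01 (737 ± 330 against 96.2 ± 67.02, 9.08-fold), TBL26 (1104 ± 711 against 128 ± 63.1) and the methionine sulfoxide reductase gene MSRB6 (133 ± 92.0 against 14.4 ± 4.03; above the floor on 2 Col-0 arrays, 7.92-fold). QQS, an orphan gene that affects starch (195 ± 8.48 against 40.2 ± 38.1; above the floor on 2 Col-0 arrays, 6.45-fold), and ZW9 (579 ± 98.5 against 119 ± 69.5) were higher as well. The call of CSLA01 (adjusted p = 0.021) ended without Col-0 array 3 (0.13), npr1 array 1 (0.087) or npr1 array 2 (0.062). In mock-treated Col-0 the signals were 27.7 ± 18.9 for UGT73D1, 40.9 ± 18.5 for cwINV6, 322 ± 127 for MSRB6 and 867 ± 115 for TBL26.

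Of the 3 SA response genes UGT76B1 and WRKY53 (81.7 ± 4.37 against 262 ± 26.7) were lower in npr1 and GRX480 did not pass (756 ± 73.5 against 976 ± 65.2). Of these 2 passed when adjusted over the list alone. The set was lower (median log2 -1.68; adjusted p = 0.0093; adjusted p = 0.058 with an estimated correlation). Of 4 SA regulation and synthesis genes SARD4 (690 ± 156 against 1722 ± 166) and SAG101 were lower, 2 when adjusted over the list alone (set adjusted p = 0.15). SAG101 did not pass without Col-0 array 1 (adjusted p = 0.14), Col-0 array 3 (0.10), npr1 array 1 (0.052) or npr1 array 2 (0.22). It did not pass either after quantile normalization (0.063), without a trend (0.052) or in the fit of the groups compared (0.11). Photosynthesis genes were higher: 7 of 9 passed and 8 when adjusted over the list alone. SBPASE stood at 438 ± 122 against 184 ± 24.6 and PSAN at 1357 ± 548 against 557 ± 114, and the list was higher as a set (median log2 0.88; adjusted p = 5.9e-05; adjusted p = 0.29 with an estimated correlation). Of the genes of pattern-triggered immunity 1 of 5, WRKY22, was lower (adjusted p = 0.061 without npr1 array 2), and 2 when adjusted over the list alone. The set was lower (adjusted p = 0.041; adjusted p = 0.29 with an estimated correlation), and was not called without Col-0 array 3 (0.14) or npr1 array 2 (0.18) or with a 60th percentile filter (0.083). The anthocyanin genes DFR, UF3GT and 5GT lay at the floor on all Col-0 arrays. In npr1 1 of 3, 5GT, passed, and 3 when adjusted over the list alone (set adjusted p = 0.041; adjusted p = 0.29 with an estimated correlation). This set call ended without Col-0 array 3 (0.11) or npr1 array 2 (0.16) or with log2 of the value plus 32 (0.087). The call of 5GT ended without Col-0 array 1 (adjusted p = 0.067), Col-0 array 3 (0.071), npr1 array 1 (0.072) or npr1 array 2 (0.069), or with log2 of the value plus 32 (0.065). The fit called 2658 probe sets, 1354 higher and 1304 lower (1073 and 1574 after centring), with a median of all of 0.021 and 36.2% without overlap, against 10% by chance. There were 1702 calls without Col-0 array 3 and 1568 without npr1 array 1. Without npr1 array 1 or 3 more were lower than higher (835 and 733, 1244 and 1082).

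In pad2, 84 probe sets differed from Col-0. The organic cation transporter gene OCT5 was 2.68-fold higher (212 ± 32.6 against 80.0 ± 17.1, adjusted p = 0.0017), and its call held under all 18 alternatives. QQS stood at 261 ± 15.8 against 40.2 ± 38.1 (above the floor on 2 Col-0 arrays, 8.65-fold; adjusted p = 0.0067, 0.0501 without pad2 array 2, and 0.078 in the fit of the groups compared). The sugar transporter gene SWEET17 (199 ± 48.8 against 72.3 ± 7.30), the gibberellin receptor gene GID1A (68.9 ± 2.79 against 26.2 ± 6.04) and SIR (709 ± 48.0 against 399 ± 23.2) were higher. Without pad2 array 2 the adjusted p of these 3 genes was 0.15, 0.11 and 0.11, and without pad2 array 1 it was 0.12, 0.11 and 0.11. SWEET17 and SIR did not pass either without Col-0 array 1 (0.12 and 0.081), 2 (0.089 and 0.062) or 3 (0.073 and 0.073). GID1A did not pass without Col-0 array 2 (0.10), Col-0 array 3 (0.055) or pad2 array 3 (0.060). With centred arrays SWEET17 (0.052) and SIR (0.099) did not pass, nor GID1A after quantile normalization (0.052) or SWEET17 without a trend (0.055). CYP71B35 was higher (27.6 ± 1.85 against 11.8 ± 2.57; above the floor on 2 Col-0 arrays, 2.22-fold). TBL38 (54.5 ± 19.9 against 121 ± 15.1, 2.31-fold) and MAMI (335 ± 44.8 against 554 ± 9.75, 1.66-fold) were lower. The calls of CYP71B35 and MAMI ended without any 1 of the 6 arrays (adjusted p from 0.091 to 0.17 and from 0.094 to 0.14). That of TBL38 ended without any of them but pad2 array 3 (0.11 to 0.24). After quantile normalization none of the 3 passed (0.098, 0.093 and 0.067). Without a trend TBL38 (0.076) and MAMI (0.059) did not pass. CYP71B35 and TBL38 did not pass without a filter (0.078 and 0.060), in the fit of the groups compared (0.075 and 0.071) or with only probe sets listed with 1 gene (both 0.059). CYP71B35 was not called with centred arrays (0.099) or log2 of the value plus 32 (0.077) either. SIR was the 1 of 3 genes of glutathione and sulfate assimilation that passed, 2 when adjusted over the list alone (set adjusted p = 0.56). SIR was also called higher than in Col-0 in npr1 (596 ± 20.1), sid2 (628 ± 129) and pad4 (815 ± 170). The call in npr1 ended without Col-0 array 3 (adjusted p = 0.051) or npr1 array 1 (0.054), and that in sid2 without sid2 array 1 (0.076) or in the fit of the groups compared (0.058). No photosynthesis gene passed over all probe sets, 0 of 9, and 5 when adjusted over the list alone. The list was higher as a set (median log2 0.58; adjusted p = 5.9e-05; adjusted p = 0.29 with an estimated correlation). Calls in pad2 were 75 higher and 9 lower, 26 and 20 after centring, and 2005 probe sets had an unadjusted p under 0.05. The count was 24, 19 and 31 without Col-0 array 1, 2 or 3 and 10, 5 and 33 without pad2 array 1, 2 or 3; 22.7% of probe sets had no overlap, against 10% by chance.

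The pad4 comparison addresses a regulator upstream of salicylate. All 9 photosynthesis genes were higher than in infected Col-0, and 9 when adjusted over the list alone. SBPASE stood at 1103 ± 140 against 184 ± 24.6, PRK at 2008 ± 136 against 368 ± 79.2. LHCB4.2 stood at 4357 ± 821 against 858 ± 222 and PSAN at 2705 ± 161 against 557 ± 114. The means of these 4 genes lay below their mock means. FAMA, the 1 guard cell marker measured, was higher as well (59.3 ± 5.71 against 32.04 ± 5.31, adjusted p = 0.012). It did not pass after quantile normalization (0.090), with centred arrays (0.22) or without Col-0 array 2 (0.056). The list was higher as a set (median log2 1.69, or 1.52 relative to all probe sets; adjusted p = 1.5e-07; adjusted p = 0.19 with an estimated correlation). BCAT4 stood at 1040.2 ± 428 against 71.3 ± 35.5. MSRB6 stood at 748 ± 499.6 against 14.4 ± 4.03 and MSRB5 at 209 ± 119 against 11.9 ± 4.62 (each above the floor on 2 Col-0 arrays, 41.3-fold and 13.7-fold higher). TBL26 stood at 2772 ± 1261 against 128 ± 63.1, CSLA01 at 2032 ± 1002 against 96.2 ± 67.02 and the lectin gene JAL23 at 1174 ± 641 against 65.6 ± 25.7. JMT, raised by infection, was higher still in pad4 (1702 ± 690 against 568 ± 119.6, adjusted p = 0.021). Its call ended with centred arrays (adjusted p = 0.098) and without Col-0 array 1 (0.067), Col-0 array 3 (0.056), pad4 array 1 (0.10) or pad4 array 2 (0.066). BSMT1 stood at 6041 ± 901 against 3720.3 ± 432 and did not pass (adjusted p = 0.55). In mock-treated Col-0 MSRB5 stood at 346 ± 57.4, CSLA01 at 38.7 ± 10.5 and JAL23 at 59.8 ± 21.1. The 3 anthocyanin genes were higher in pad4, 3 when adjusted over the list alone, by at least 4.25-fold for DFR and at least 6.09-fold for UF3GT (set adjusted p = 0.069, 0.033 with centred arrays and 0.030 without a filter).

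The osmotin-like gene OSM34 stood at 10.1 ± 12.2 against 270 ± 93.1 (above the floor on 1 pad4 array, 14.5-fold) and ATGLR1.2 at 47.1 ± 27.1 against 336 ± 17.7 (7.92-fold). Also lower were CXE20 at 18.8 ± 4.57 against 195 ± 71.4, UGT73D1 at 25.5 ± 19.0 against 266 ± 118 and cwINV6 at 31.2 ± 23.5 against 208 ± 59.4. The last 3 were above the floor on 2 pad4 arrays and 10.1-fold, 10.7-fold and 7.29-fold lower with values raised to it. Of the SA regulation and synthesis genes 2 of 4 were lower, 2 when adjusted over the list alone: SAG101 (47.5 ± 20.9 against 202 ± 46.1) and SARD4 (533 ± 222 against 1722 ± 166; set adjusted p = 0.11). Of the SA response genes WRKY53 (139 ± 86.3) and GRX480 (615 ± 138) were lower, 2 when adjusted over the list alone (set adjusted p = 0.069). WRKY53 did not pass without pad4 array 1 (adjusted p = 0.081) or in the fit of the groups compared (0.062), nor GRX480 without pad4 array 2 (0.097). PUB23 (64.0 ± 32.4 against 232 ± 71.8), BIK1 (131 ± 33.7 against 325 ± 118) and EFR were the 3 of 5 genes of pattern-triggered immunity that were lower, 3 when adjusted over the list alone. The set was lower (adjusted p = 0.043; adjusted p = 0.29 with an estimated correlation), and was not called with centred arrays (0.077), with a 60th percentile filter (0.072), without Col-0 array 3 (0.096) or without pad4 array 2 (0.10). EFR did not pass without Col-0 array 1 (adjusted p = 0.056), Col-0 array 3 (0.069), pad4 array 1 (0.070) or pad4 array 2 (0.092). The SA response set passed without pad4 array 3 (0.049) and without a filter (0.030). WRKY6 was lower (88.3 ± 42.7 against 338 ± 75.4), and the beta-glucosidase gene PYK10, abundant in roots, was higher (357 ± 287 against 15.7 ± 6.91, adjusted p = 0.0053; 12.3-fold with values raised to the floor).

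The fit called 6037 probe sets in pad4, 3614 higher and 2423 lower, and 49.7% had no overlap, against 10% by chance. The median of all was 0.17 on the authors' scale and -0.30 after centring, and the split was 2673 higher and 2857 lower after quantile normalization and 1837 and 5181 after centring. The pad4 arrays correlated with the mean of the mock arrays at r = 0.831, 0.798 and 0.782, the infected Col-0 arrays at 0.634 to 0.647. Array 3 of pad4 had an actin 3' to 5' ratio of 3.97, the highest of the 24 arrays.

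The sid2 comparison addresses induced salicylate synthesis. All 3 SA response genes were lower in sid2, 3 when adjusted over the list alone. UGT76B1 stood at 75.0 ± 15.7 against 1232 ± 260 (16.4-fold, adjusted p = 1.3e-04), WRKY53 at 60.3 ± 7.57 against 262 ± 26.7 and GRX480 at 395 ± 97.5 against 976 ± 65.2. The set was lower (median log2 -2.12; adjusted p = 1.3e-05; adjusted p = 0.0014 with an estimated correlation). UGT73D1 stood at 10.1 ± 3.42 against 266 ± 118 (above the floor on 1 sid2 array, 21.6-fold). MMP, a matrix metalloproteinase gene, stood at 6.58 ± 4.79 against 29.2 ± 9.63 (above the floor on 1 sid2 array, 2.67-fold; adjusted p = 0.071 in the fit of the groups compared). UGT76E1 stood at 14.6 ± 13.6 against 89.4 ± 9.90 (above the floor on 1 sid2 array, 5.88-fold) and cwINV6 at 20.8 ± 6.00 against 208 ± 59.4. SARD4 (747 ± 88.0 against 1722 ± 166) and the receptor gene EFR (15.3 ± 3.89 against 41.0 ± 3.29) were lower. Higher in sid2 were CYP71B22 (179.9 ± 67.4 against 14.8 ± 6.21; above the floor on 2 Col-0 arrays, 11.2-fold), the peptide gene RALFL34 (168 ± 34.8 against 46.5 ± 14.6) and SWEET17 (276 ± 65.5 against 72.3 ± 7.30). Their mock values were 14.1 ± 4.68, 467 ± 70.5 and 443 ± 19.5. CPUORF47 (31.4 ± 8.37 against 9.06 ± 4.62, 2.78-fold) and PPR596 (15.2 ± 2.45 against 5.77 ± 5.11, 1.38-fold), above the floor on 1 Col-0 array, were also higher. The call of CPUORF47 ended without Col-0 array 3 (adjusted p = 0.054). That of PPR596 ended without any 1 of the 6 arrays but Col-0 array 3 (0.058 to 0.24), without a filter (0.057), with log2 of the value plus 32 (0.19) and in the fit of the groups compared (0.16).

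PDF1.2A was higher in sid2 (233 ± 288), at least 11.5-fold above infected Col-0, where it lay at the floor. The call (adjusted p = 0.031) ended without Col-0 array 1 (0.15), Col-0 array 2 (0.057), sid2 array 2 (0.15) or sid2 array 3 (0.062), or with log2 of the value plus 32 (0.095). Of the photosynthesis genes 1 of 9, PSAN, was higher, and 4 when adjusted over the list alone (set adjusted p = 0.0057; adjusted p = 0.43 with an estimated correlation; 0.13 without sid2 array 1). PSAN itself did not pass without Col-0 array 2 (adjusted p = 0.059) or sid2 array 1 (0.051). In the fit 1699 probe sets were called, 692 higher and 1007 lower, with a median of all of 0.00094 and 29.6% without overlap, against 10% by chance. The count was 1066 without Col-0 array 1, 1056 without Col-0 array 3 and 1053 without sid2 array 1. The sid2 plants carry other growth wording in the labels, so a batch cannot be told apart from this genotype.

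**Figure D3:**
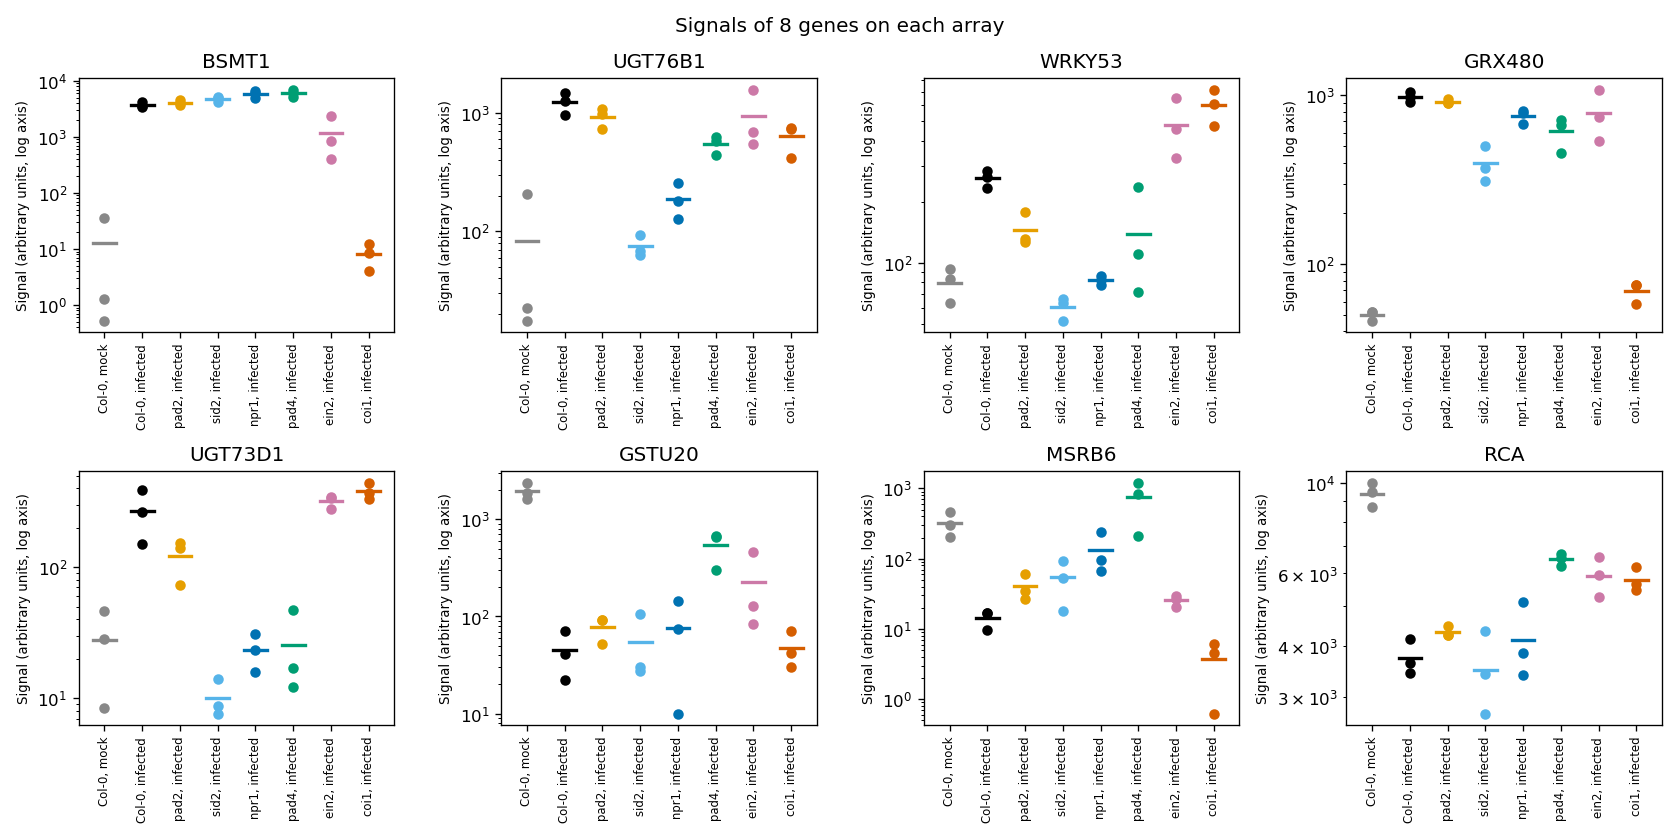
Signals of 8 genes (y axis, arbitrary units on a log scale) in the 8 groups (x axis); points are arrays and lines are the means of 3 arrays. BSMT1 stands at 8.30 in coi1 against 3720.3 in infected Col-0, UGT76B1 at 75.0 in sid2 against 1232, and WRKY53 at 601 in coi1 against 60.3 in sid2.

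Contrasts between mutants share no Col-0 arrays. Against sid2, pad4 had higher photosynthesis genes, 9 of 9 and 9 when adjusted over the list alone, with SBPASE at 1103 ± 140 against 262 ± 107. The list was higher as a set (median log2 1.16, or 0.95 relative to all probe sets; adjusted p = 3.3e-06; adjusted p = 0.18 with an estimated correlation). It also had more BCAT4 (1040.2 ± 428 against 111 ± 122), GSTU20 (547 ± 213 against 54.3 ± 44.3), MSRB6 (748 ± 499.6 against 54.4 ± 36.9), GH9B8 (78.1 ± 45.6 against 9.65 ± 7.41; above the floor on 2 sid2 arrays, 5.59-fold) and UGT76B1 (543 ± 92.7 against 75.0 ± 15.7). PYK10 was higher (357 ± 287 against 11.3 ± 6.29; above the floor on 2 sid2 arrays, 14.6-fold with values raised to the floor). All 3 SA response genes were higher, 3 when adjusted over the list alone (set adjusted p = 0.13, and 0.0499 without pad4 array 1). GRX480 and WRKY53 did not pass without pad4 array 3 (both adjusted p = 0.11). GRX480 did not pass either without pad4 array 1 (0.11), sid2 array 1 (0.13) or sid2 array 2 (0.083), nor WRKY53 without sid2 array 3 (0.054). With centred arrays the log2 difference was 0.17 for GRX480 (adjusted p = 0.63) and 0.56 for WRKY53 (0.16), and in the fit of the groups compared the adjusted p was 0.10 and 0.095. WRKY53 did not pass after quantile normalization (0.051) or with array weights (0.088) either. Lower in pad4 were OSM34 (10.1 ± 12.2 against 806 ± 473; above the floor on 1 pad4 array, 40.2-fold), CCOAMT (59.4 ± 17.9 against 666 ± 327), STR18 (62.6 ± 27.5 against 587 ± 115) and UGT71B5 (35.2 ± 11.4 against 303 ± 129), and BGLU46 (14.1 ± 7.96 against 101 ± 21.5; above the floor on 2 pad4 arrays, 5.63-fold). So were PUB23 (64.0 ± 32.4 against 209 ± 19.6), WRKY6 (88.3 ± 42.7 against 255 ± 38.0) and SAG101 (47.5 ± 20.9 against 125 ± 22.4). The fit called 4700 probe sets, 3039 higher and 1661 lower, 1962 and 1882 after quantile normalization and 1205 and 4356 after centring, with a median of all of 0.21. There were 3073 calls without pad4 array 1, and 41.0% had no overlap, against 10% by chance. With the array number as a block, IGPS (adjusted p = 0.031) and GR1 (0.045) passed as well.

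Between npr1 and sid2, 21 probe sets were called, 17 higher and 4 lower in npr1 (5 and 4 after quantile normalization, 8 and 5 after centring), and 59 with the array number as a block. Of all probe sets 1500 had an unadjusted p under 0.05 and 13.1% had no overlap, against 10% by chance. The carboxypeptidase-like gene scpl46 was 2.32-fold higher in npr1 (114 ± 12.9 against 50.9 ± 17.1, adjusted p = 0.0068, 0.074 without npr1 array 1, and 0.38 in the fit of the groups compared). The subtilase gene ATSBT5.2 was 2.09-fold higher (212 ± 13.3 against 103 ± 25.8). Its call (adjusted p = 0.041) ended without npr1 array 1 (0.14), 2 (0.13) or 3 (0.097) or sid2 array 2 (0.21) or 3 (0.135). It also ended after quantile normalization (0.080), with centred arrays (0.082), without a filter (0.053), without a trend (0.070) and in the fit of the groups compared (0.315). None of the SA response genes passed, 0 of 3, and 1 when adjusted over the list alone. The set was higher in npr1 (median log2 0.96; adjusted p = 0.0065; adjusted p = 0.030 with an estimated correlation). GRX480 stood at 756 ± 73.5 against 395 ± 97.5 and UGT76B1 at 187 ± 63.9 against 75.0 ± 15.7. The count was 7 without npr1 array 1, 16 without npr1 array 3 (7 higher and 9 lower), 37 without sid2 array 1 and 8 without sid2 array 2. Photosynthesis was higher as a set (0 of 9 genes, 2 when adjusted over the list alone; adjusted p = 0.012; adjusted p = 0.56 with an estimated correlation). This call ended without npr1 array 1 (0.50), sid2 array 2 (0.11) or sid2 array 3 (0.18). The anthocyanin set was called higher without npr1 array 3 (0.042).

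Between coi1 and sid2, signals differed in both directions. WRKY53 (601 ± 119.98 against 60.3 ± 7.57), UGT76B1 (631 ± 185 against 75.0 ± 15.7), cwINV6 (669 ± 76.6 against 20.8 ± 6.00), GSTU27 (403 ± 58.3 against 47.8 ± 9.75) and SARD4 (1638 ± 291 against 747 ± 88.0) were higher in coi1. UGT73D1 was higher too, at 379 ± 53.9 against 10.1 ± 3.42 (above the floor on 1 sid2 array, 32.8-fold), and NANA at 118 ± 54.7 against 9.05 ± 5.13 (above the floor on 2 sid2 arrays, 10.0-fold). TBL26 was lower (16.4 ± 11.5 against 415 ± 235; above the floor on 2 coi1 arrays, 25.1-fold). BSMT1 (8.30 ± 4.13 against 4714 ± 484), UGT76E12 (10.1 ± 7.92 against 2231 ± 292), TBL41 (8.43 ± 3.11 against 168 ± 44.3), UGT85A3 (11.4 ± 1.35 against 216 ± 30.2), OPCL1 (186 ± 19.6 against 775 ± 79.0) and GH3.5 (39.1 ± 9.36 against 170.3 ± 53.7) were lower. With values raised to the floor, BSMT1, TBL41 and UGT85A3, above it on 1 coi1 array, and UGT76E12, above it on 2, were 418-fold, 15.0-fold, 18.4-fold and 167-fold lower. JMT and PDF1.2A lay at the floor in coi1, at least 81.0-fold and at least 11.0-fold lower. All 3 SA response genes passed, 2 higher and 1 lower, and 3 when adjusted over the list alone (set adjusted p = 0.86). No list was called as a set by camera. Fry called auxin (median log2 -1.335, fry adjusted p = 0.0024) and glutathione and sulfate assimilation (-0.3675, fry adjusted p = 8.8e-04). The guard cell marker FAMA was lower in coi1 (23.5 ± 2.61 against 45.4 ± 3.64, adjusted p = 0.0092). Of the 3 reference genes 1, TIP41L, was higher (112 ± 4.13 against 77.8 ± 9.38, adjusted p = 0.041), 1 when adjusted over the list alone (set adjusted p = 0.95). It did not pass after quantile normalization (0.18), with centred arrays (0.31), without a filter (0.052) or without any 1 of the 6 arrays but sid2 array 3 (0.071 to 0.15). The fit called 5110 probe sets, 3261 higher and 1849 lower (1976 and 2538 after centring), with a median of all of 0.17 and 44.9% without overlap, against 10% by chance.

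Genes that responded to infection were then followed as sets in each mutant, chosen without infected Col-0 and without that mutant. In pad4 the 4194 probe sets lowered by infection had a median 1.13 (log2) above infected Col-0 and the 2350 raised ones a median of -0.77, or 0.96 and -0.94 relative to all probe sets. Both were called (adjusted p = 0.0034 and 0.0011 with an estimated correlation), with 2355 of the lowered set called higher and 9 lower, and 1285 of the raised set called lower and 86 higher. In coi1 the medians were 0.53 for the lowered and -0.43 for the raised set (adjusted p = 0.099 and 9.4e-04 with an estimated correlation). In ein2 they were 0.52 and -0.34, the latter -0.22 without ein2 array 3 (adjusted p = 0.048 and 0.0033 with an estimated correlation). The lowered and raised sets had medians of 0.48 and -0.26 in npr1 (adjusted p = 0.052 and 0.099 with an estimated correlation) and 0.38 and -0.17 in pad2 (adjusted p = 0.079 and 0.051 with an estimated correlation). With the preset correlation all of these sets were called. Every mutant was set against the same 3 infected Col-0 arrays, so the medians are not independent. Direct differences between coi1, ein2, npr1 and pad2 use no Col-0 array. Their medians ran from 0.02 (ein2 minus npr1) to 0.17 (coi1 minus pad2) over lowered sets. Over raised sets they ran from -0.35 (coi1 minus pad2) to -0.08 (coi1 minus ein2). The lowered-set medians of these mutants are thus of like size, which does not show that the same probe sets differ in each. Direct contrasts of these pairs called from 346 (npr1 and pad2) to 4956 (coi1 and npr1) probe sets. A shift of the Col-0 arrays stays open as a part of these medians. In sid2 the lowered set had a median of 0.25, and 0.11 without sid2 array 1 (adjusted p = 2.4e-07; adjusted p = 0.21 with an estimated correlation). The raised set had a median of -0.04 and was not called (adjusted p = 0.086), and was called after quantile normalization (-0.07) and centring (-0.08).

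**Figure D4:**
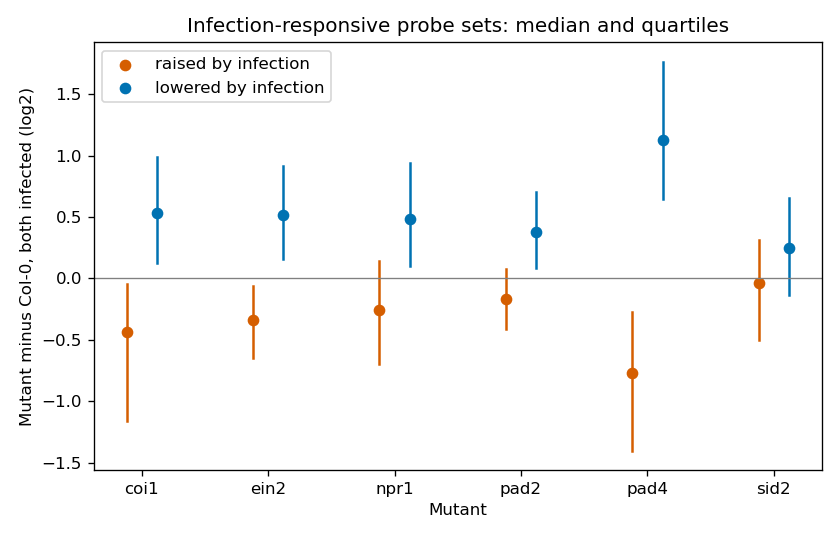
Mutant minus Col-0, both infected (log2, y axis), for probe sets raised and lowered by infection in each of 6 mutants (x axis); points are medians and bars run from the lower to the upper quartile. The medians of the lowered sets run from 0.25 in sid2 to 1.13 in pad4, and those of the raised sets from -0.77 in pad4 to -0.04 in sid2.

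Differences from Col-0 were compared between mutants across probe sets. In groups simulated without change that share the Col-0 arrays, r was 0.50 and the covariance 0.093, so the covariance in excess of that value is given. It was highest for npr1 with pad4 (0.50; r = 0.72) and was 0.32 for npr1 with sid2 (r = 0.77), 0.30 for pad4 with sid2 (r = 0.52), 0.28 for pad2 with pad4 (r = 0.64), 0.26 for ein2 with pad4 (r = 0.50) and 0.24 for coi1 with ein2 (r = 0.55). Of the probe sets called in both npr1 and sid2, 544 were higher and 720 lower in both, against 58.7 and 82.3 by chance, and 0 went opposite ways. Between coi1 and sid2 the excess was -0.12 (r = -0.04), with 142 higher in both, 22 lower in both and 261 opposite, against 64.7, 61.6 and 136.6 by chance. These chance counts treat the comparisons as independent. The shared Col-0 arrays raise agreement and lower opposite counts without any mutant effect. No simulated value is given for the counts, so agreement above the chance counts is not evidence of a like effect. Opposite counts above theirs are not explained by the sharing. The F test over the 7 infected genotypes called 8097 of 15961 probe sets, 50.7%.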

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

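The tests of the npr1 and sid2 pattern were chosen after the result had been seen, and so were the repeat of the coi1 set without ein2 and the test of each pad4 array. The contrasts between mutants stood out because they test a difference between 2 genotypes' departures from infected Col-0 directly. They called 4700 probe sets for pad4 against sid2, 21 for npr1 against sid2 and 5110 for coi1 against sid2.

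The pad4 arrays lay closer to the mock arrays than the other infected genotypes did, and over probe sets lowered by infection pad4 exceeded infected Col-0 by a median of 1.13 (log2). After quantile normalization the median was 0.97, which argues against the authors' scaling as the whole source. Centring moved the median of all probe sets from 0.17 to -0.30, so the size of the 1.13 depends on the scale. Relative to all probe sets it was 0.96 on the authors' scale. With each pad4 array left out in turn it was at least 1.03, which argues against any 1 of them as the source. The 1.23 without array 3, the pad4 array least like the mock arrays, decides nothing. Direct differences between mutants use no infected Col-0 array. Over lowered sets the median was 0.96 for pad4 minus sid2. It was -0.58, -0.64, -0.69 and -0.75 for coi1, ein2, npr1 and pad2 minus pad4. These values argue against a shift of the Col-0 arrays as the whole source of the 1.13, but not as a part of it. Of 2350 probe sets raised by infection 86 were higher in pad4 than in Col-0 and 1285 lower, and JMT, raised by infection in Col-0, was higher in pad4 (1702 ± 690 against 568 ± 119.6). A weaker response of most of these genes in pad4 is a possible explanation, but a difference that exists without infection, or a different bacterial load, stays open because no mutant was mock-treated and no bacterial count was used here.

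Little separated npr1 from sid2, with 21 calls, or 39 higher and 20 lower in npr1 with the array number as a block. Too few arrays to separate any pair would have left other pairs with as few, and 0 of the other 14 direct pairs of mutants had 100 calls or fewer. The lowest of these was 346, for npr1 and pad2. Outside the pairs of mutants, pad2 against infected Col-0 had 84 calls, so a low count is not particular to npr1 and sid2. The direct contrast of npr1 with sid2 holds no Col-0 array, so shared Col-0 arrays could not have made its count low. They bear only on the covariance of the npr1 and sid2 differences from Col-0, which exceeded the simulated value by 0.32. A like effect of losing salicylate synthesis and losing its receptor could account for the low count, as a hypothesis that was not tested. Against a wholly like effect, the SA response set was called higher in npr1 than in sid2, also with an estimated correlation. Mean GRX480 and UGT76B1 were higher in npr1, though no gene of that set passed over all probe sets. The low count does not show that the genotypes are equal, since 1500 probe sets had an unadjusted p under 0.05, and the batch of sid2 stays open.

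Among probe sets called in both coi1 and sid2, 261 of 425 (61.4%) went opposite ways, against 51.9% by chance, and after quantile normalization 64.2% did, which argues against the authors' scaling. Of these, 139 were lower in coi1 and higher in sid2 (42.4 by chance) and 122 the other way (94.2 by chance). Another 142 probe sets were higher in both (64.7 by chance). The chance values treat the comparisons as independent, but both use the same Col-0 arrays. That sharing raises agreement without any mutant effect, so the 142 cannot be read against the 64.7. It lowers opposite calls, so it does not explain their excess. As a hypothesis, some genes that need salicylate may be higher without the jasmonate and coronatine receptor. This concerns only the 122 probe sets higher in coi1 and lower in sid2. A difference that exists without infection, or a different bacterial load, stays open here too. No mutant was mock-treated and no bacterial count was used. Over 649 probe sets lower in npr1 and sid2 than in ein2 and pad2, coi1 exceeded Col-0 by a median of 0.60, or 0.44 relative to all probe sets. Of these, 138 were called higher and 10 lower (camera p = 3.0e-07, and p = 0.22 with an estimated correlation). A set chosen as lower in sid2 cannot speak to the 139 probe sets that were higher in sid2, where the excess over chance was larger. The SA response list, with 3 of its 21 genes measured, does not decide, since its genes went different ways in coi1. Its median log2 was -0.99 (camera adjusted p = 0.091, fry adjusted p = 2.8e-06). That is the value of UGT76B1, which did not pass (631 ± 185 against 1232 ± 260). GRX480 was 14.1-fold lower in coi1, while it was called lower in sid2 but not in npr1. WRKY53 was higher in coi1. Chosen without the ein2 arrays, 217 probe sets, 198 of them in the first set, had a median of 0.37, past the bound set for it, but that bound left out the shift of all probe sets: relative to it the median was 0.21, with 33 called higher and 5 lower, so a part of the ein2 arrays stays open, as does the batch of sid2, on whose arrays both sets rest.

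Other splits of the 6 arrays of each comparison were counted, and 10 splits are too few for a share under 0.05. In each of the 10 comparisons 1 of 10 splits, the real one, reached the real count. The real count and the highest other were 10106 and 0 for infection in Col-0, 2470 and 1 for coi1, 921 and 1 for ein2, 2658 and 2 for npr1, 84 and 2 for pad2, 6037 and 1 for pad4, and 1699 and 1 for sid2. Against sid2 they were 4700 and 1 for pad4, 21 and 10 for npr1, and 5110 and 1 for coi1. For the F test 1 of 100 splits of the 21 infected arrays, the real one, reached 8097 calls. The highest other gave 738, which argues against a chance division of the arrays. Shuffling treats the arrays as independent, so it cannot exclude a batch shared by the arrays of a group.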

How the results depend on the processing

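The fit without ein2 array 3 and pad4 array 3 was chosen after the data had been seen. No named gene or list reversed. Correlations of pairs of mutants were checked for a move but not for a change of sign. Of 15 pairs 4 moved with log2 of the value plus 32, 3 without a filter and 1 with a 60th percentile filter. The balance of higher and lower calls turned for infection, coi1 and pad4 after quantile normalization and centring. After centring it turned for ein2, npr1, pad4 against sid2 and coi1 against sid2 as well, as the report gives. It also turned for ein2 in the fit of the groups compared (132 higher and 175 lower) and without the 2 arrays (155 and 177), and for npr1 with log2 of the value plus 32 (1270 and 1353) and with probe sets listed with 1 gene (642 and 683). Counts that moved by over 1.5 times are given here against the counts of the report; the cause was not tested except where stated. Quantile normalization gave 35 calls for pad2 and 9 for npr1 against sid2, and centring gave 46 and 13. Without a filter npr1 against sid2 gave 9, and without a trend pad2 gave 48 and npr1 against sid2 13. Array weights gave 4345 for coi1, 4042 for npr1, 1232 for pad2, 2947 for sid2 and 51 for npr1 against sid2. Fits of only the groups compared gave 307 for ein2, 149 for pad2, 3069 for pad4 against sid2 and 2 for npr1 against sid2. The block on array number gave 1633 for ein2, 230 for pad2, 59 for npr1 against sid2 and 5506 for pad4 against sid2. In the last 2 it changed no call of a named gene or list other than those in the report; in npr1 the anthocyanin set then had an adjusted p of 0.051. Residuals of 22 of 24 arrays correlated best with arrays of their own number in other groups, and 43 of 84 same-numbered pairs exceeded 0.1, a hint from the data that the labels do not give. With the block the simulated covariance was 0.083, leaving an excess of 0.33 for npr1 with sid2 and -0.11 for coi1 with sid2. Without ein2 array 3 and pad4 array 3 there were 332 for ein2, 206 for pad2 and 38 for npr1 against sid2.

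A 2-fold threshold, which by construction removes small changes, left 1483 for coi1, 558 for ein2, 1353 for npr1, 3511 for pad4, 872 for sid2, 2627 for pad4 against sid2, 2915 for coi1 against sid2 and 4652 for the F test. Using only probe sets listed with 1 gene tested fewer probe sets and gave 5339 for infection, 1184 for coi1, 381 for ein2, 1325 for npr1, 23 for pad2, 3077 for pad4, 860 for sid2, 2388 for pad4 against sid2, 7 for npr1 against sid2, 2623 for coi1 against sid2 and 4177 for the F test. Of the list shifts, 2 were called with an estimated correlation and 30 with fry. The probe sets raised by infection passed as lower in sid2 after quantile normalization (median -0.068), centring (-0.079) and without a filter (-0.043).

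Leaving out each array in turn gave 1594 to 1877 calls for coi1, 261 to 1042 for ein2, 1568 to 2326 for npr1, 5 to 33 for pad2, 1053 to 1603 for sid2, 3073 to 4496 for pad4 against sid2 and 7 to 37 for npr1 against sid2. Within 1.5 times of the reported counts were infection (9322 to 9464), pad4 (4358 to 6074), coi1 against sid2 (4047 to 4560) and the F test (6883 to 8200). Of 369 values of named genes, 345 stayed on their side of the threshold after quantile normalization and 341 after centring, and of 2214 with an array left out 1993 did. Low signal limits the folds: values near the floor of an array carry little information on size.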

Other observations

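The gene families of this part were chosen after the annotation had been seen, and their members are named after their values were seen. All 8 measured autophagy genes rose with infection in Col-0 on each of the 3 scales between arrays, with ATG8H at 552 ± 15.5 against 52.1 ± 12.6 and ATG8D at 219 ± 37.8 against 44.1 ± 4.29 (mean signal ± SD, n = 3 arrays per group). The family rose as a set (median log2 1.54 relative to all probe sets; camera adjusted p = 0.0013; adjusted p = 0.39 with an estimated correlation), at 1.37 after quantile normalization and 2.04 after centring. Of 68 chloroplast-encoded probe sets 38 fell and 0 rose on the authors' scale (median log2 -1.35 relative to all probe sets; adjusted p = 0.0036; adjusted p = 0.63 with an estimated correlation), while with centred arrays 18 fell and 4 rose.

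Of 38 UGT glycosyltransferase genes 10 were lower and 1 was higher in coi1 than in Col-0, both infected, with UGT76E11 at 120 ± 29.7 against 445 ± 169 and UGT74B1 at 274 ± 85.8 against 627 ± 190 (median log2 -0.46 relative to all probe sets; adjusted p = 2.9e-04; adjusted p = 0.077 with an estimated correlation). The family was lower on each of the 3 scales, with adjusted p of 6.9e-04 after quantile normalization and 0.0046 after centring. Of 5 WRKY genes 3 were higher in coi1, with WRKY47 at 119 ± 10.7 against 41.6 ± 4.49 (set adjusted p = 0.045; adjusted p = 0.38 with an estimated correlation), and 4 were lower in npr1, with WRKY47 at 21.2 ± 6.08 (set adjusted p = 0.035; adjusted p = 0.59 with an estimated correlation). Both directions held on each of the 3 scales.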
